A study of Mus musculus with 23 samples.

How the data were processed

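RNA was measured in tumor-adjacent mammary fat pad from 23 female mice in 4 groups, with 1 library per mouse. The libraries were non-directional and enriched for poly(A) RNA, so no strand was read. Per the labels, samples with an RNA integrity number above 5 were used. The deposited files give, for each of 115088 transcripts, estimated counts (not normalized) and TPM (transcript abundances scaled to the same total within each library). The deposited effective lengths were the same in every library. The submitters' notes name edgeR, limma and the GRCm38 mouse genome without versions, and the program that made the transcript estimates is not given in the sources used here. TPM values were used only in 1 alternative.

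Of the listed transcripts, 114200 matched the GENCODE M21 annotation of GRCm38, and 888 did not. The unmatched ones held at most 0.208% of the estimated counts of any library. Estimated counts were summed per gene (47311 genes) and rounded, and 1 gene name was updated to its current symbol. No transcript of the mitochondrial genome was listed, so RNA quality could not be judged from mitochondrial reads. Whether mitochondrial RNA was counted under other genes was not tested. The predicted gene Gm28661, among the 5 highest genes of many libraries, held 3.93% of the counts in lean anti-PD-1 4 and 1.27% in obese IgG2a 5.

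Genes were kept by edgeR's filterByExpr (minimum count 10, by group), which left 19882. Counts were scaled by TMM, and 1 mean per group was fitted to all 23 libraries with edgeR 4.0.16 in R 4.3.3, with robust dispersions. The 5 comparisons were obese against lean mice under each antibody, anti-PD-1 against IgG2a in each weight group, and the difference between the last pair (the interaction). Each used edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called, and is said below to have risen or fallen, at an adjusted p under 0.05. The common biological coefficient of variation was 0.805 and the median prior degrees of freedom were 3.38. Counts scaled to library size (CPM) are given as mean ± SD over the libraries of a group. Estimated counts are not molecules, so depth speaks for counting error only. Log2 fold changes are those of the fit, with their standard error (SE).

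The 36 gene lists (507 members, from general knowledge of adipose metabolism, immune states and cell types) were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list moves more than the other genes. It was repeated with the correlation estimated from the data, and fry tested whether members move, on balance, one way. Members called are counted over all genes tested, and again adjusted over the list alone. A list score is the mean log2 CPM of its members in a library.

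The comparisons, lists and most alternatives were chosen before the data were examined, as was the rule for naming genes. The rule takes, in each comparison, the 8 called genes of largest fold change in each direction with a mean of at least 4 CPM. It adds the 3 members of smallest p in each list called by camera, and Lep, Adipoq, Pdcd1 and Cd274 throughout. Where no gene was called, it takes the 3 of smallest p in each direction. Predicted genes without a common name are counted and not named. The text describes a part of the genes that the rule selects. Alb, Hmga2, Fosl1, Mmp13, Mki67, Glycam1, Madcam1, Ccl21a, Chst4 and Cd79a were chosen after their values were seen.

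The alternatives were DESeq2 (version 1.42.0) size factors or test, voom with or without library quality weights, no filter or a stricter one (1 CPM in 5 libraries), transcript length offsets and log2(TPM + 1) with limma-trend. Others were covariates for lymph node, mammary epithelium and skeletal muscle scores, only the groups compared, and each library left out in turn. After the data were seen, fits were added with only the libraries above, or only those below, a B cell score of 4, and without obese IgG2a libraries 2 and 5 together. A list of 22 liver genes was also added then. The fit and the list tests were also tested on simulated data with known changes. No library was left out of the tests reported first, and no deposited per-sample value column was unread.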

Results

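RNA was sequenced from the mammary fat pad beside a breast tumor in 23 female C57BL/6J mice. Obese mice had eaten food with 60% of its energy as fat between 8 and 26 weeks of age. The labels give lean mice low-fat food with 10% of its energy as fat, while the treatment text of every sample describes the high-fat food alone. Tumors grew from 250000 E0771 cells, a mouse mammary carcinoma line that here carried luciferase, placed in mammary gland 4. From day 3 the mice received 200 µg of anti-PD-1, an antibody that blocks an inhibitory receptor of T cells, or of its IgG2a isotype control every 3 days until day 21. There were 5 lean IgG2a, 5 lean anti-PD-1, 5 obese IgG2a and 8 obese anti-PD-1 mice. Each library held between 49438121 (lean IgG2a 3) and 77369057 (lean IgG2a 5) estimated counts. The ranges were 58307652 to 65465950 in lean anti-PD-1, 50204192 to 68700109 in obese IgG2a and 55138742 to 72943643 in obese anti-PD-1 mice. Between 14806 (lean anti-PD-1 4) and 18403 (obese IgG2a 1) genes had at least 10 counts. The labels give no batch.

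The fat pad holds fat cells, milk-duct epithelium and, at its inguinal end, a lymph node. Libraries fell into separate sets by their B cell genes, with a list score of 5.25 to 8.36 in 11 libraries and at most -0.42 in the other 12. The high score occurred in 4 of 5 lean IgG2a, 3 of 5 lean anti-PD-1, 2 of 5 obese IgG2a and 2 of 8 obese anti-PD-1 libraries. Stroma genes of lymph nodes rose with it, and the first principal component (34.1% of the variance) separated the same sets of libraries. Genes of the liver were high in obese IgG2a 5 alone (Alb 6363 CPM, at most 222 elsewhere). Skeletal muscle genes were high in lean IgG2a 1 and 2, lean anti-PD-1 1 and 2 and obese IgG2a 3.

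**Figure D1:**
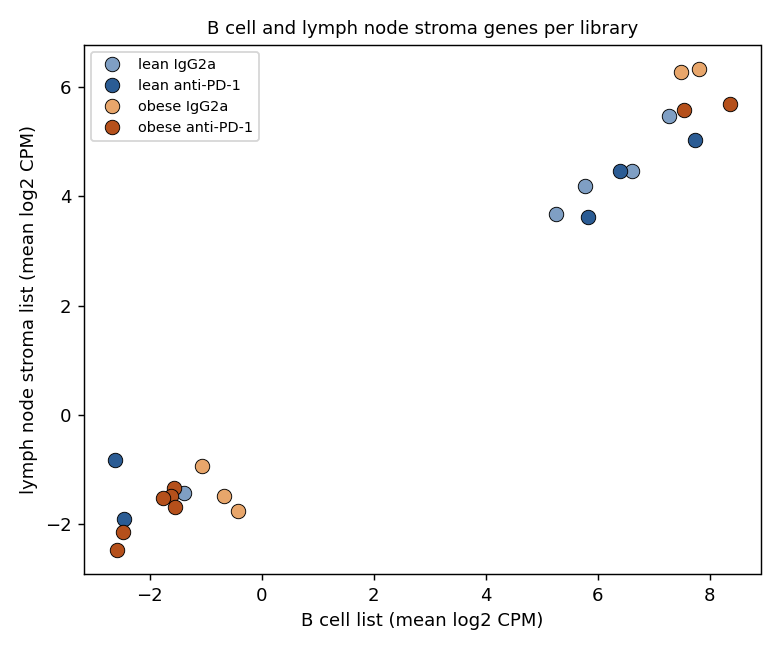
B cell list score (mean log2 CPM) against lymph node stroma list score for each of the 23 libraries, by group. The 11 libraries with a B cell score of at least 5.25 lie apart from the 12 with at most -0.42.

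The first comparison asked how diet-induced obesity changed the fat pad without checkpoint blockade. In obese IgG2a mice the genes that make fatty acids from sugar fell steeply, together with genes of heat-producing fat cells and of the respiratory chain. As lists, genes of enlarged fat tissue, macrophages and complement were higher and epithelial genes lower. With an estimated correlation neither these (0.147, 0.147, 0.0892 and 0.147) nor the respiratory chain list (0.0792) passed. Of the 19882 genes tested, 1152 changed, 532 upward and 620 downward.

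Acly, whose enzyme makes the acetyl-CoA used for fatty acids, fell by 4.72 log2 units in obese IgG2a mice (SE 0.387, adjusted p = 1.5e-07). It is ENSMUSG00000020917, on GRCm38 chromosome 11 from 100476353 to 100528000. Its level was 3858 ± 1220 CPM in lean and 147 ± 32.5 CPM in obese mice (SD, n = 5 each), and the obese libraries (at most 192) lay below every lean one (at least 2560). Aacs (ENSMUSG00000029482, chromosome 5, 125475814 to 125517410), which activates acetoacetate for lipid synthesis, fell by 3.05 (SE 0.242, adjusted p = 1.2e-07), from 516 ± 141 to 62.2 ± 11.8 CPM. The carboxylase gene Acacb fell by 4.04, and the elongase gene Elovl6 fell by 5.91. Slc2a5 (ENSMUSG00000028976, chromosome 4, 150119283 to 150144169) encodes a fructose carrier and fell by 9.01 (SE 0.969, adjusted p = 6.0e-06), from 92.3 ± 24.6 to 0.180 ± 0.112 CPM. In the fatty acid synthesis list, 17 of 18 members fell (17 adjusted over the list alone). Its median log2 fold change was -3.58 (camera adjusted p = 1.7e-36), and it held with an estimated correlation (0.0144).

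The thermogenic list also held with an estimated correlation (adjusted p = 0.0144). In it, 11 of 15 members fell (12 adjusted over the list alone) and the median was -3.49 (2.4e-17). Cidea (ENSMUSG00000024526, chromosome 18, 67343604 to 67367785), a lipid droplet gene of brown-type fat, fell by 6.46 (SE 0.537, adjusted p = 1.5e-07), from 286 ± 197 to 3.24 ± 1.86 CPM. Ucp1, the uncoupling protein that releases heat, fell by 9.35 (SE 1.86, adjusted p = 0.00477), from 186 ± 249 to 0.282 ± 0.316 CPM. Elovl3 fell by 7.49 and Cpt1b fell by 3.49. Mitochondrial genes moved less and more evenly. Of the 22 oxidative phosphorylation genes 17 fell (22 adjusted over the list alone), with a median of -1.22 (1.4e-25; adjusted p = 0.0792 with an estimated correlation). Uqcrc2 (ENSMUSG00000030884, chromosome 7, 120635176 to 120659524), a complex III subunit, fell by 1.51 (SE 0.172, adjusted p = 1.1e-05), from 304 ± 42.5 to 106 ± 17.8 CPM. Ndufs1 fell by 1.21 and Sdha fell by 1.40. Of 17 cholesterol synthesis genes 6 fell (10 lower and 1 higher adjusted over the list alone), with a median of -0.82 (1.1e-05, or 0.387 with an estimated correlation). Fdft1 fell by 1.48 and Insig1 fell by 2.95.

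Markers of fat cells moved much less. In that list 4 of 16 members fell (5 lower and 1 higher adjusted over the list alone), among them Retn (fell by 2.06), Slc2a4 and Adrb3, and the median was -0.66 (5.5e-04, or 0.633 with an estimated correlation). The list median was -1.20 in the libraries with a high B cell score and -1.02 in the others, where lean IgG2a 5 is the only lean control. Adipoq did not pass (-0.66, adjusted p = 0.535). Of 10 genes linked to fat tissue expansion 6 rose (8 adjusted over the list alone), with a median of 2.99 (1.9e-06, or 0.147 with an estimated correlation). In the libraries with a high B cell score that median was 1.56, and the list stayed called. Sfrp5, a secreted Wnt antagonist, rose by 5.31 (SE 1.08, adjusted p = 0.00544), from 9.27 ± 10.2 to 369 ± 361 CPM, and Bmp3 by 2.85. Lep, the satiety hormone of fat cells, was higher without passing (2.53, SE 0.770, adjusted p = 0.0536; 216 ± 123 and 1246 ± 1190 CPM).

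**Figure D2:**
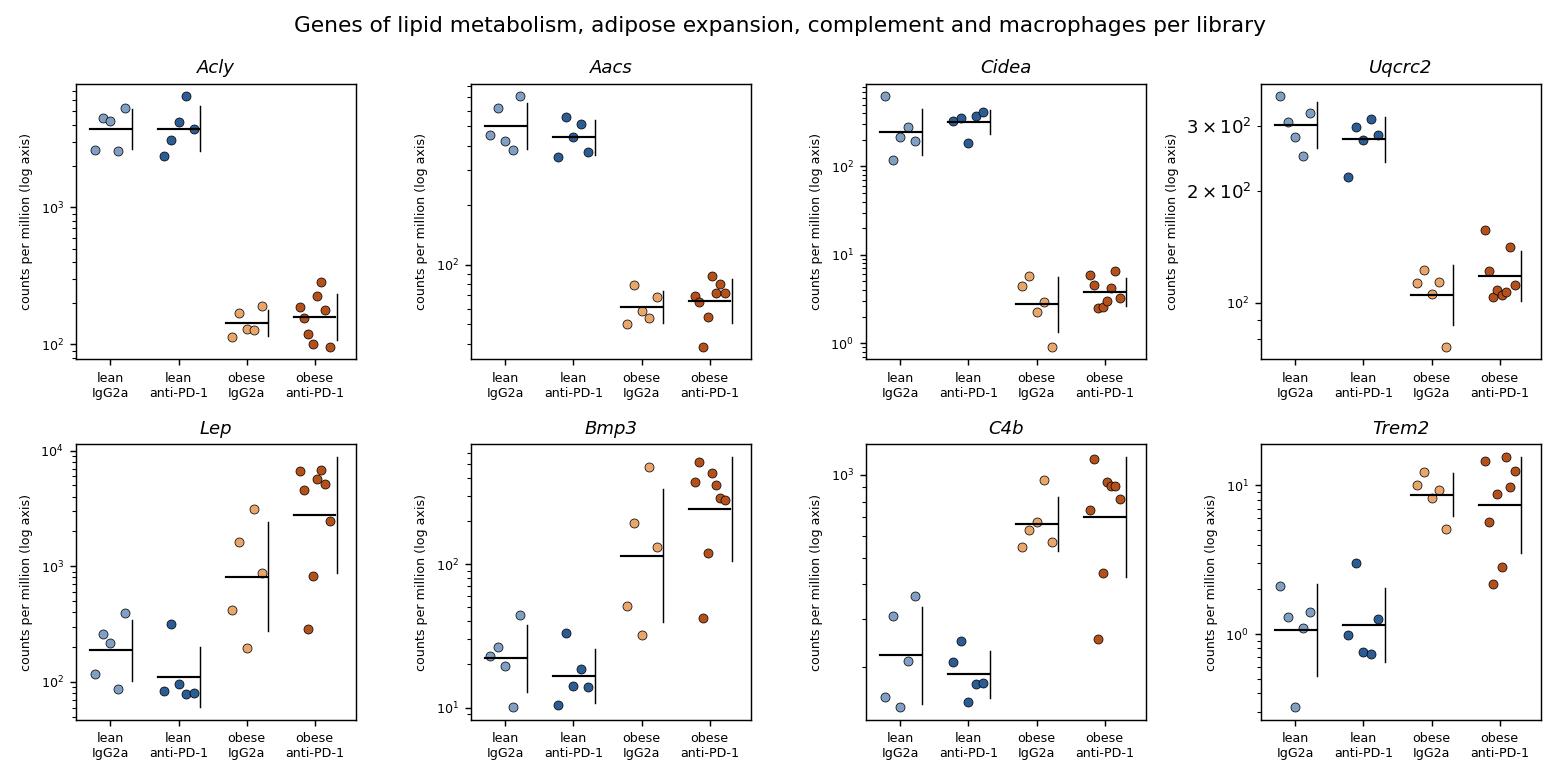
CPM (log axis) of 8 genes in each library, by group, with a line at the mean and a bar of ±1 SD of the log10 values. Acly, Aacs, Cidea and Uqcrc2 were lower in every obese library than in every lean one.

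Immune genes rose in part. Of 15 macrophage genes 3 rose (7 adjusted over the list alone), with a median of 0.88 (8.2e-05, or 0.147 with an estimated correlation), and Itgam, the integrin of myeloid cells, rose by 2.12 (SE 0.375, adjusted p = 0.00175). The list of lipid-associated macrophages, which clear dying fat cells, had 6 genes up and 2 down of 15 (7 and 2 adjusted over the list alone; median 1.06, 0.00165, or 0.402 with an estimated correlation). Trem2, the lipid receptor of these cells (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), rose by 2.86 (SE 0.566, adjusted p = 0.0043), from 1.24 ± 0.636 to 9.04 ± 2.68 CPM. Mmp12 rose by 3.12 and Fabp5 fell by 1.79. The monocyte attractant Ccl2 rose by 3.37 and was the called member of the M1-like list (1 of 15, 2 adjusted over the list alone; median 1.44, 0.00585, or 0.502 with an estimated correlation). In the complement list 3 of 12 rose (6 adjusted over the list alone; median 1.09, 0.001, or 0.0892 with an estimated correlation). C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) rose by 1.52 (SE 0.337, adjusted p = 0.00948), from 236 ± 95.7 to 677 ± 166 CPM.

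Neutrophil genes had a median of 4.02 (1.6e-05, or 0.147 with an estimated correlation), with 1 of 13 called (9 adjusted over the list alone). S100a8 rose by 4.29, a call that ended without lean IgG2a 5 (4.19, adjusted p = 0.0527). The proliferation list rose (median 1.95, 3.4e-07; 0.423 with an estimated correlation; 3 of 18 called, 6 adjusted over the list alone). Its called genes Cdk1, Aurka and Cenpf each lost the call without 6 or more of the 10 libraries, with an adjusted p of up to 0.226 for Cenpf (without obese IgG2a 5, where it changed by 2.29 in place of 3.29). Interferon-induced genes were slightly higher as a list (0.52, 0.00207; 0.633 with an estimated correlation; 1 of 21 called, 1 adjusted over the list alone).

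Among structural lists, mammary epithelium was lower (median -1.42, 2.9e-09, or 0.147 with an estimated correlation). Of its 16 genes 4 fell over all genes tested and 14 adjusted over the list alone. Krt19, a ductal keratin, fell by 1.39 (adjusted p = 0.0345; 450 ± 70.5 to 171 ± 27.9 CPM) and lost the call without any 1 of the 10 libraries (up to 0.0985 without lean IgG2a 2, where it fell by 1.30). Epidermis genes were lower (-3.76, 0.001; 0.423 with an estimated correlation; 1 of 9 called, 6 adjusted over the list alone), with a median of -2.22 without lean IgG2a 5. Skeletal muscle genes were lower (-3.00, 0.00585; 0.682 with an estimated correlation; 0 of 13 called, 0 adjusted over the list alone), which ended without lean IgG2a 1 (-0.22, adjusted p = 0.104) and without obese IgG2a 2 and 5 together (-2.26, 0.0849). Its median was -8.09 without obese IgG2a 3. The largest rises were of liver genes, Cps1, Ambp, Kng1, Fga, Slco1b2, Ahsg, Mug1 and Gc, by 10.15 to 10.86. They rested on obese IgG2a 5. Without that library Cps1 changed by 3.91 (adjusted p = 0.455), and the calls of these genes also ended without lean IgG2a 1, 3 or 5.

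The total of 1152 genes moved by more than 1.5 times when single libraries were left out. It was 716 without obese IgG2a 2, 549 without obese IgG2a 5, 495 without lean IgG2a 1, 545 without lean IgG2a 2 and 559 without lean IgG2a 5. It was also lower with the epithelium score as a covariate (310). That score was higher in every lean IgG2a library (at least 5.14) than in any obese one (at most 4.27), so this fit cannot decide whether lost epithelium is a cause. The total was lower too in the 12 libraries without a high B cell score, where lean IgG2a 5 is the only lean control. In those 12 the calls of complement (median 0.42, adjusted p = 0.592) and muscle (-1.80, 0.154) ended with smaller medians. Those of macrophages (0.76, 0.174) and lipid-associated macrophages (1.11, 0.0676) ended with medians about as large as before. In the 11 others those of lipid-associated (0.34, 0.33), interferon (0.22, 0.0805), epidermis (-2.26, 0.0695) and muscle genes (-2.17, 0.495) ended. Complement stayed called in these 11, with a median of 0.53 in place of 1.09.

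The second comparison asked what obesity did under checkpoint blockade. The same metabolic groups fell in obese anti-PD-1 mice, and the genes of fat tissue expansion rose. As lists, complement was higher and epithelial genes lower, while the macrophage list did not pass. Of the 12 lists called, 0 passed with an estimated correlation. In all, 1999 genes changed, 1034 upward and 965 downward, or 1108 without lean anti-PD-1 4.

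Fatty acid synthesis fell in 14 of 18 members (16 adjusted over the list alone; median -2.97, 3.8e-26, or 0.0519 with an estimated correlation). Acly fell by 4.55 (SE 0.316, adjusted p = 5.5e-09), from 3960 ± 1554 CPM (n = 5) to 169 ± 65.4 CPM (n = 8). Aacs fell by 2.73 (SE 0.202, adjusted p = 1.4e-08), and Acacb fell by 3.78. Slc2a5 fell by 9.43 (SE 0.794, adjusted p = 1.1e-07), from 98.5 ± 38.3 to 0.145 ± 0.191 CPM. Thermogenic genes fell in 10 of 15 (11 adjusted over the list alone; median -2.95, 2.9e-12, or 0.0519 with an estimated correlation), and Cidea fell by 6.34 (adjusted p = 5.5e-09). Ucp1 fell by 7.42 (adjusted p = 0.00167). Of 22 oxidative phosphorylation genes 21 fell (21 adjusted over the list alone; median -1.25, 2.2e-24, or 0.0698 with an estimated correlation), Uqcrc2 among them (fell by 1.22), as did Sdhb. Of 17 cholesterol synthesis genes 8 fell (10 adjusted over the list alone; median -1.15, 1.7e-07, or 0.28 with an estimated correlation), and Mvd, which acts in the mevalonate pathway, fell by 2.08.

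In the expansion list 8 of 10 rose (9 adjusted over the list alone; median 4.91, 2.0e-11, or 0.0519 with an estimated correlation). Its median was 2.82 in the libraries with a high B cell score, where it stayed called. Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877) rose by 4.95 (SE 0.838, adjusted p = 6.5e-04), from 131 ± 105 CPM (n = 5) to 4058 ± 2558 CPM (n = 8). Sfrp5 (ENSMUSG00000018822, chromosome 19, 42197971 to 42202252) rose by 8.15 (SE 1.22, adjusted p = 1.9e-04), from 2.55 ± 1.95 to 726 ± 347 CPM. Bmp3 rose by 4.06. Cdkl4, a kinase gene (ENSMUSG00000033966, chromosome 17, 80523550 to 80577813), rose by 8.71 (SE 1.29, adjusted p = 1.7e-04), from 0.0422 ± 0.0943 to 19.6 ± 12.5 CPM. Other genes near 0 in lean fat pad also rose, to means of 15.5 to 34.4 CPM: Folh1, Itgad, Tph2, Ptchd4, Gabrr2 and Unc79. The adipocyte marker list did not move as one (1 higher and 4 lower of 16, 2 and 4 adjusted over the list alone; median 0.20, mean 0.11, camera downward, 0.36), and Adipoq did not pass (0.21, adjusted p = 0.853).

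Complement rose in 4 of 12 members and fell in 1 (4 and 1 adjusted over the list alone; median 0.74, 0.00621, or 0.115 with an estimated correlation). C4b rose by 2.01 (SE 0.323, adjusted p = 3.8e-04), from 191 ± 38.2 to 770 ± 291 CPM, and Serping1 by 1.70. The list call ended in the 12 libraries without a high B cell score (0.56, adjusted p = 0.148). The macrophage list had a median of 0.05 (0.869) and the lipid-associated list of 0.74 (0.127, with 4 genes up and 2 down). Mammary epithelium fell in 13 of 16 members (14 adjusted over the list alone; median -1.66, 8.6e-12, or 0.0919 with an estimated correlation). Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665) fell by 1.91 (SE 0.336, adjusted p = 8.9e-04), from 747 ± 378 to 199 ± 114 CPM, and Krt7 and Krt18 fell too. With the epithelium score as a covariate, 59 genes were called in place of 1999. Every lean anti-PD-1 library had a higher epithelium score (at least 4.75) than any obese one (at most 4.74). Since the score separates the groups compared, this fit cannot decide whether lost epithelium is a cause.

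Skeletal muscle genes fell in 8 of 13 members (11 adjusted over the list alone; median -6.04, 0.0243, or 0.896 with an estimated correlation). The list call ended without lean anti-PD-1 1 (-5.93, 0.195) or 2 (-4.67, 0.296). The calls of Myh4 (fell by 9.90) and Ckm ended without lean anti-PD-1 2 (-8.05 and -7.93, adjusted p = 0.0709 and 0.0613). Mmd2 fell by 9.32 (adjusted p = 3.8e-04). Further lists passed without holding when libraries were left out or with an estimated correlation (0.896 for each). The matrix list rose (1.15, 0.0303; 1 of 22 called, 10 adjusted over the list alone) and lost the call without 6 of 13 libraries (up to 0.176, without lean anti-PD-1 1, with a median of 1.00). The type I interferon list (-0.47, 0.0345; 1 of 21 called, 0 adjusted over the list alone) lost it without 5 (up to 0.379 without lean anti-PD-1 2, where the median was -0.03). The T cell list (-0.49, 0.0303; 0 of 18 called, 0 adjusted over the list alone) lost it without 8 (up to 0.195 without lean anti-PD-1 1, where it turned to 0.10). MHC class I genes (-0.43, 0.00621; 0 of 12 called, 0 adjusted over the list alone) kept it. All of these turned direction in the 11 libraries with a high B cell score, to -0.61, 0.51, 0.78 and 0.25, and the muscle call ended there (-5.62, 0.236). With the lymph node score as a covariate the matrix (0.43, 0.277) and T cell (-0.24, 0.49) calls ended with smaller medians, and the interferon (-0.52, 0.0564) and muscle (-6.69, 0.0564) calls with medians as large as before. The stricter filter ended the interferon (-0.44, 0.0759) and T cell (-0.47, 0.0535) calls, and the 12 libraries without a high B cell score that of T cells (-0.32, 0.584).

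**Figure D3:**
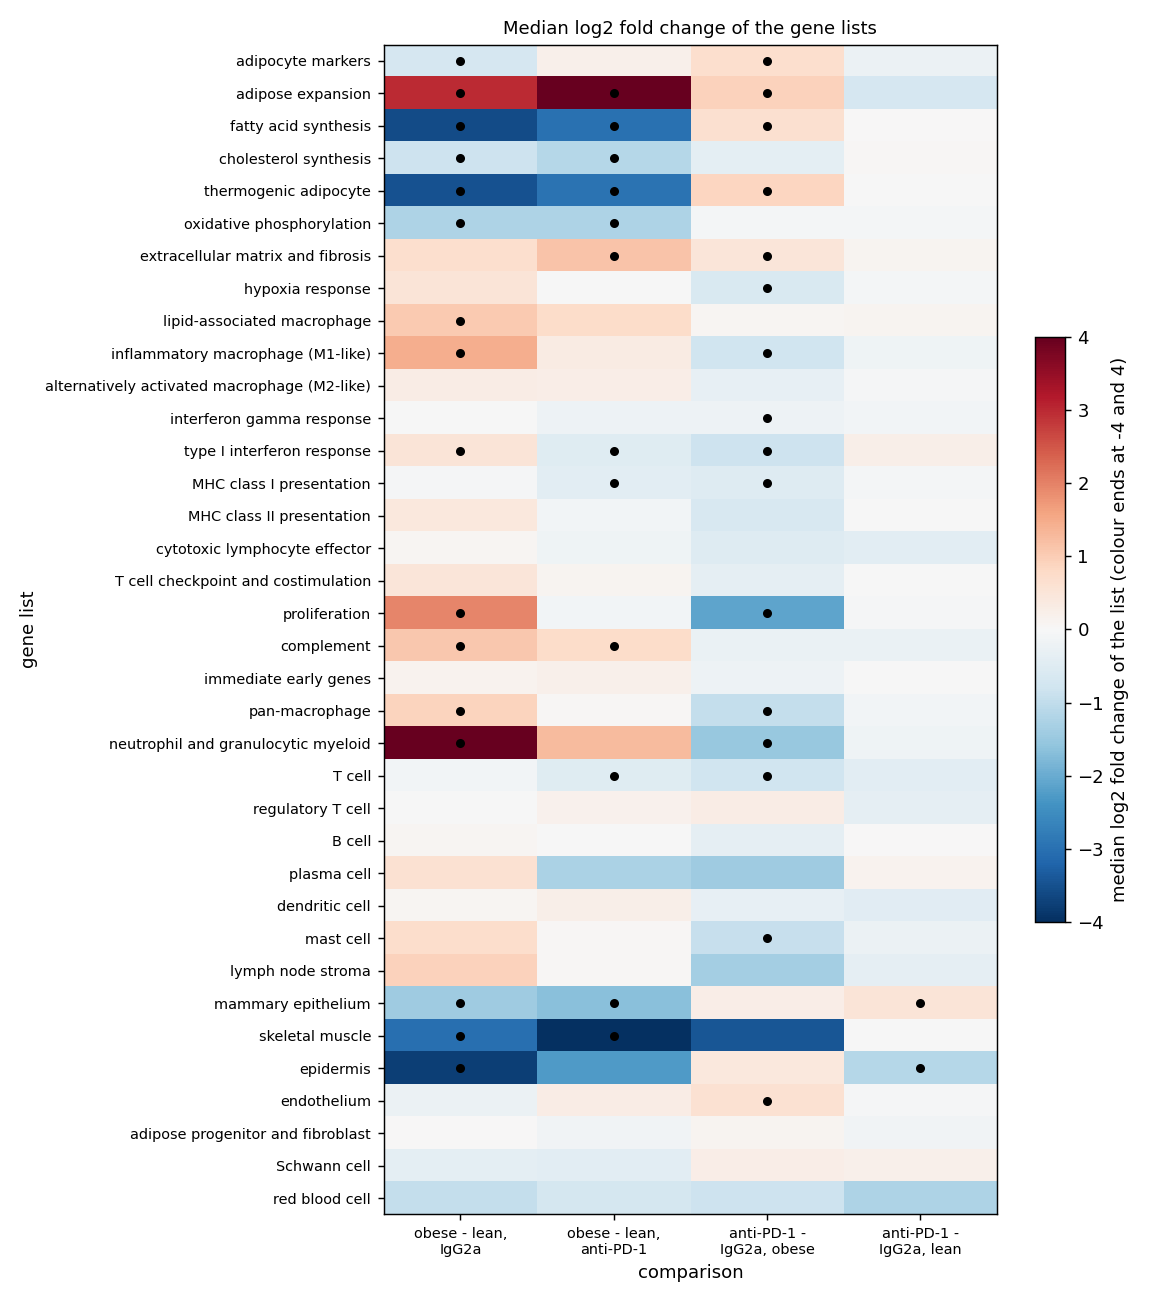
Median log2 fold change of the 36 gene lists (lines) in the 4 comparisons of groups (columns; colours end at -4 and 4), with a dot where the camera adjusted p was under 0.05. Fatty acid synthesis stood at -3.58 and -2.97 in the obesity comparisons and at 0.02 for anti-PD-1 in lean mice.

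The obesity effects shared no library between the antibodies. Of the genes that rose, 136 did so under both antibodies (27.7 if independent), and of those that fell 436 (30.1 if independent). None of the genes called in both moved in opposite directions. Over the 19882 genes the fold changes correlated at r = 0.530 (Spearman's rho 0.475), across genes, which are not independent replicates. High B cell scores were commoner in lean libraries with IgG2a (4 of 5 against 2 of 5) and with anti-PD-1 (3 of 5 against 2 of 8). Epithelial genes were lower in obese mice under both. The overlap and correlation were not separated from such shared differences in tissue make-up.

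The third comparison asked what PD-1 blockade changed in the fat pad of obese mice. Cell cycle, macrophage, hypoxia and interferon genes were lower as lists in treated mice, and genes of fat cells and of fatty acid synthesis slightly higher. Of the 16 lists called, 0 passed with an estimated correlation, and few of their members passed. In all, 107 genes changed, of which 106 fell and 1 rose.

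Of the genes that fell, 89 had their highest value in obese IgG2a 5 and 98 in that library or obese IgG2a 2. The largest falls were of liver genes. Apob, the lipoprotein gene (ENSMUSG00000020609, chromosome 12, 7977648 to 8016835), fell by 11.45 (SE 1.97, adjusted p = 0.0328), from 149 ± 331 CPM (n = 5) to 0.0498 ± 0.0569 CPM (n = 8). Mug1, Bhmt, Cps1, Pzp, Fga, Apoh and Mat1a fell too, with log2 fold changes of -11.13 (Mug1) to -9.71 (Mat1a). Without obese IgG2a 5 none of these passed (Apob changed by -3.67, adjusted p = 0.514). Away from the liver, Slc2a1, the main glucose carrier and a hypoxia gene (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983), fell by 1.52 (SE 0.298, adjusted p = 0.0328), from 78.6 ± 51.3 to 27.4 ± 8.97 CPM. Egln3, an oxygen sensor (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), fell by 1.85 (SE 0.40, adjusted p = 0.0421). Aurka, a mitotic kinase (ENSMUSG00000027496, chromosome 2, 172356190 to 172370535), fell by 2.13 (SE 0.466, adjusted p = 0.0436), from 18.8 ± 9.88 to 4.28 ± 3.07 CPM. Ms4a7, a macrophage gene (ENSMUSG00000024672, chromosome 19, 11321039 to 11336146), fell by 1.49 (SE 0.339, adjusted p = 0.0498), from 13.4 ± 6.04 to 4.77 ± 1.53 CPM. Lynx1, a modulator of nicotinic receptors (ENSMUSG00000022594, chromosome 15, 74747852 to 74753046), rose by 0.99 (SE 0.225, adjusted p = 0.0498), from 21.4 ± 6.04 to 42.5 ± 14.6 CPM. Each of these 5 lost its call without 8 or 9 of the 13 libraries, with the highest adjusted p without obese IgG2a 5 (0.504 for Slc2a1 and Lynx1, 0.514 for Egln3, Aurka and Ms4a7). Their log2 fold changes there were -1.15 (Slc2a1), -1.48 (Egln3), -1.94 (Aurka), -1.45 (Ms4a7) and 0.84 (Lynx1), much nearer to those over all libraries than for the liver genes.

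Of the lists called, proliferation had the lowest median (-2.12, 2.2e-15, or 0.307 with an estimated correlation), with 1 of 18 members called and 15 adjusted over the list alone. The macrophage list had a median of -0.96 (2.4e-06, or 0.173 with an estimated correlation), with 1 of 15 called and 7 adjusted over the list alone. Hypoxia genes had a median of -0.62 (4.1e-04, or 0.173 with an estimated correlation), with 2 of 14 called and 5 adjusted over the list alone. The type I interferon list had a median of -0.84 (9.0e-08, or 0.423 with an estimated correlation), with 0 of 21 called and 5 adjusted over the list alone. Oas1a, an antiviral enzyme gene, did not pass (-1.13, adjusted p = 0.122). Neutrophil genes (-1.51, 1.1e-04, or 0.381 with an estimated correlation), the M1-like list (-0.79, 0.00193; 0.512) and mast cell genes (-0.94, 0.00565; 0.499) were lower with 0 members called, and 0 adjusted over the list alone. In the 11 libraries with a high B cell score the hypoxia (-0.05, 0.519), interferon (-0.21, 0.274) and mast cell (-0.16, 0.166) lists lost the call and the M1-like list turned (0.19). The proliferation, macrophage and neutrophil lists kept theirs with each library left out and in both sets of libraries, but their size moved. The proliferation median was -0.45 in the libraries with a high B cell score and -3.64 in the others. The neutrophil median was -0.69 and -0.93 there, and -0.88 without obese IgG2a 3. The type I interferon median was -0.55 without that library, and the mast cell median was -0.57 without obese IgG2a 1 and -2.05 without obese anti-PD-1 3, where the M1-like median was -1.30.

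Adipocyte markers (median 0.68, 0.00427, or 0.714 with an estimated correlation), fatty acid synthesis (0.64, 0.00237; 0.714), expansion genes (0.93, 0.00427; 0.599) and endothelium (0.61, 0.00427; 0.714) were higher with 0 members called, and 0 adjusted over the list alone. The adipocyte and endothelium calls ended without obese IgG2a 5 (0.49, adjusted p = 0.0718, and 0.47, 0.0707). Adipocyte markers, fatty acid synthesis and endothelium turned in the 11 libraries with a high B cell score (-0.32, -0.16 and -0.05), and the expansion list lost its call there (0.83, adjusted p = 0.243). Without obese IgG2a 2 and 5 together the adipocyte (0.56, 0.0501) and endothelium (0.49, 0.122) calls ended. The fatty acid synthesis median was 0.42 without obese IgG2a 3, and those of expansion and endothelium were 1.59 and 0.95 without obese IgG2a 4. The thermogenic list (median 0.85, mean 0.17, 0.0289; 0.714 with an estimated correlation; 2 higher and 1 lower adjusted over the list alone) lost its call without obese anti-PD-1 1 (0.50, 0.0739) or obese IgG2a 3 (0.68, 0.0633), and its median was 0.56 without obese IgG2a 1. The matrix list (0.49, 0.0289, or 0.725 with an estimated correlation) lost it without 5 of 13 libraries (up to 0.516 without obese IgG2a 3, with a median of 0.21). The same library gave the highest adjusted p for interferon gamma response genes (-0.20, 0.0371; 0.714 with an estimated correlation; lost without 7, up to 0.136 with a median of -0.10). It did so too for MHC class I (-0.51, 0.0427; 0.714; without 6, up to 0.521 with -0.22) and T cells (-0.81, 0.047; 0.822; without 8, up to 0.733, where the median turned to 0.12). The T cell list also turned with the lymph node covariate (0.16) and lost its call with DESeq2 size factors (-0.81, 0.0562). With that covariate the thermogenic (0.64, 0.054), matrix (0.10, 0.303), interferon gamma (-0.11, 0.182) and MHC class I (-0.18, 0.113) calls ended. In the libraries with a high B cell score those of the thermogenic (0.26, 0.832), matrix (0.27, 0.274) and T cell (-0.10, 0.302) lists ended and the interferon gamma list turned (0.25). In the others the matrix (0.22, 0.267), MHC class I (-0.12, 0.82) and T cell (-0.43, 0.404) calls ended. None of the members of these 5 lists passed over all genes tested, nor, outside the thermogenic list, adjusted over the list alone. Lists of cytotoxic lymphocyte effectors (-0.50, 0.129) and T cell checkpoint genes (-0.37, 0.0641) did not pass. Pdcd1, the target of the antibody (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), did not pass (-1.29, adjusted p = 0.776; 4.75 ± 5.66 and 1.94 ± 3.61 CPM), nor did its ligand gene Cd274 (-0.04, adjusted p = 0.959; 32.1 ± 5.50 and 31.2 ± 9.24 CPM).

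**Figure D4:**
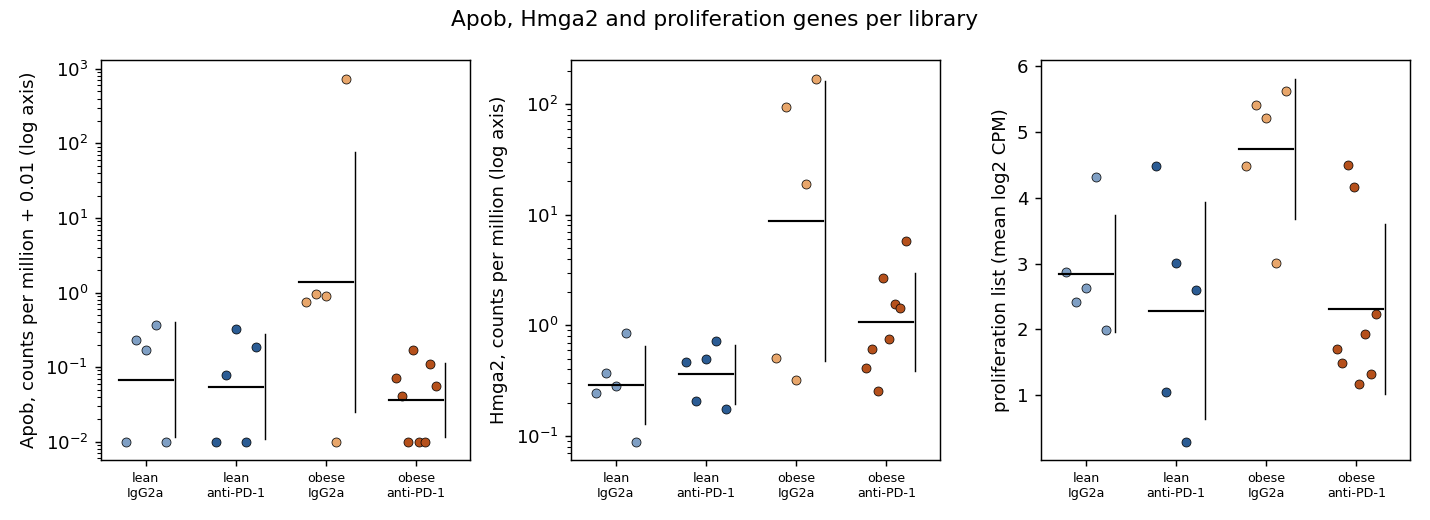
Apob (CPM + 0.01, log axis), Hmga2 (CPM, log axis) and the proliferation list score (mean log2 CPM) in each library, by group, with a line at the mean and a bar of ±1 SD (of log10 values on the log axes). Obese IgG2a 5 stands at 740 CPM for Apob, and obese IgG2a 2, 4 and 5 have 94.2, 19.0 and 170 CPM of Hmga2 against at most 5.84 elsewhere.

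With a smallest adjusted p of 0.0328, near the threshold of 0.05, the count of 107 changed widely when single libraries were left out. It was 0 without obese anti-PD-1 1, 2, 5, 6 or 7 and without obese IgG2a 2 or 5, and 13 without obese anti-PD-1 8. It was 228 without obese anti-PD-1 3, and 295, 208 and 643 without obese IgG2a 1, 3 and 4. It was 0 without obese IgG2a 2 and 5 together, and 0 with voom or with limma-trend on TPM.

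The fourth comparison asked what PD-1 blockade changed in lean mice. No gene passed in edgeR, with 472 at an unadjusted p under 0.05. DESeq2 called 22, voom 0, voom with quality weights 1 and limma-trend on TPM 0. In simulated data with these group sizes, 67% of genes changed 4-fold and 10% of those changed 2-fold were recovered, so most 2-fold changes would have gone undetected.

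Fkbp5, a gene induced by glucocorticoids (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), was among the genes of smallest p and did not pass (0.88, SE 0.203, adjusted p = 1). Its level was 33.0 ± 8.70 CPM with IgG2a and 60.8 ± 14.5 CPM with anti-PD-1 (n = 5 each). The others, Prss57, Pappa2, Lgals2, Dmrta2 and Olr1, had means under 1 CPM in both lean groups. As a list, mammary epithelium was higher (median 0.52, 0.00104, or 0.944 with an estimated correlation), with 0 of 16 called and 0 adjusted over the list alone. It lost the call without lean anti-PD-1 2 (0.26, 0.0961) or 4 (0.40, 0.0829) and stood at -0.08 in the libraries with a high B cell score. Krt8, a luminal keratin, did not pass (0.92, adjusted p = 1). Epidermis genes were lower (-1.15, 0.00741; 0.944 with an estimated correlation; 0 of 9 called, 0 adjusted over the list alone). That call ended without 6 of 10 libraries and turned without lean IgG2a 5 (0.16, 0.3), and the median was -3.86 without lean anti-PD-1 4. Cytotoxic effectors (-0.41, 0.373), checkpoint genes (median -0.02, mean 0.00, camera upward, 0.812), Pdcd1 (0.60), Cd274 (-0.44), Lep (-0.71) and Adipoq (-0.37) did not pass.

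The last comparison asked whether the response to PD-1 blockade differed between obese and lean mice. No gene passed in edgeR (smallest adjusted p 0.396), with 1449 at an unadjusted p under 0.05. DESeq2 called 50, voom 1, voom with quality weights 623 and limma-trend on TPM 0. In simulated data 37% of genes with a 4-fold difference and 4% of those with a 2-fold one were recovered.

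As lists, camera called 8, with no member called over all genes tested and 2 (hypoxia genes) adjusted over the list alone. Proliferation (median -2.12, 7.4e-09), type I interferon (-1.08, 7.4e-09) and macrophage genes (-0.80, 1.7e-04) responded more downward in obese than in lean mice, and expansion genes more upward (1.74, 4.8e-04). These 4 kept the call with each library left out and had an adjusted p of 0.602 with an estimated correlation. Without lean anti-PD-1 1 the proliferation median was -1.06, and without lean anti-PD-1 2 the interferon median was -0.69. In the libraries with a high B cell score the proliferation median was -0.83 and the macrophage median -0.48, both still called. The interferon list stood at 0.14 in those libraries. Neutrophil genes (-0.58, 0.00805, or 0.732 with an estimated correlation) lost the call without obese anti-PD-1 1 (-0.47, 0.0571) or obese IgG2a 3 (-0.60, 0.0699), and both in the libraries with a high B cell score (-0.09, adjusted p = 0.216) and in the others (-0.98, 0.0846). Hypoxia genes (-0.30, 0.0204; 0.602) lost it without obese IgG2a 2 (-0.27, 0.0507) or lean anti-PD-1 2 (-0.34, 0.0717). Adipocyte markers (0.86, 0.0204; 0.893) lost it without 6 of 23 libraries (up to 0.134) and epidermis (1.76, 0.0387; 0.893) without 10 (up to 0.251). The highest adjusted p came without lean IgG2a 5, where the medians were 0.72 and 0.36. Without lean anti-PD-1 4 the epidermis median was 4.88. The neutrophil median was -0.34 without lean anti-PD-1 1, -1.08 without lean IgG2a 2 and -0.95 without lean IgG2a 4, and the hypoxia median -0.20 without obese IgG2a 5. In the libraries with a high B cell score the epidermis call ended (2.26, 0.0899), and the adipocyte and hypoxia lists turned (-0.056 and 0.28). Without obese IgG2a 2 and 5 together the adipocyte (0.80, 0.0667), hypoxia (-0.12, 0.146) and epidermis (1.63, 0.0953) calls ended. Slc2a1 (-1.79, adjusted p = 0.396), Aurka (-2.38, 0.404), Ms4a7 (-1.67, 0.42), Lep (2.42, 0.645), Sfrp5 (2.84, 0.669) and Ifit1 (-1.97, 0.517) did not pass. Nor did Olr1, B3gnt4 and Ccdc87, with means under 1 CPM in every group, or Pdcd1 (-1.89, 0.908).

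A further test asked whether genes moved by obesity moved back under PD-1 blockade. The log2 fold changes of anti-PD-1 in obese mice and of obesity in IgG2a mice correlated at r = -0.36 (Spearman's rho -0.29) over 19882 genes. Both use the obese IgG2a libraries with opposite sign, which alone makes r negative. Groups simulated without any difference, sharing those libraries, gave a mean r of -0.539 (-0.879 to 0.0734; two-sided permutation p = 0.384 from 1000 shuffles). The covariance was -0.311 and its simulated value -0.306. With the shared controls split between the comparisons, r was -0.0132. Between obese and lean mice, whose comparisons share no library, the anti-PD-1 fold changes correlated at r = 0.0662 (rho 0.0669).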

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

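All tests of explanations in this part were chosen only after the result they address was seen, except the counts of other splits. Over 508 groups of library values (88 genes, 36 list scores and 3 measures of depth, each in 4 groups), Dixon's test on log2 values picked out 53, where chance picks out about 1 in 20. That rate does not hold for genes at 0 CPM in all other libraries of a group, and some genes were chosen for their values. The number picked out is therefore not a measure of excess over chance. Dixon's test marks a library far from the nearest other one of its group. Camera also found 8 lists whose response to anti-PD-1 differed between obese and lean mice.

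The fall of fatty acid synthesis genes in obese mice had a median log2 fold change of -3.58 with IgG2a and -2.97 with anti-PD-1. Fewer fat cells could lower these genes, but the adipocyte markers lay above them by 2.92 and 3.17 log2 units, more than the spread of the members of both lists together (1.91 and 2.14). With IgG2a the adipocyte median was -0.66 over all libraries, but -1.20 in those with a high B cell score and -1.02 in the others. A part of the fall could thus still come from fewer fat cells. With the mammary epithelium score as a covariate at least 80.0% of the median was left (camera adjusted p = 4.0e-23 and 1.3e-14), with 11 and 7 members called lower. Under each antibody every lean library had a higher epithelium score (at least 5.14 and 4.75) than any obese one (at most 4.27 and 4.74). Since the scores do not overlap, this fit cannot decide whether lost epithelium is a cause. Among anti-PD-1 libraries without a high B cell score the median was -3.07, which argues against lymph node as the whole cause. High-fat food may lower these genes without obesity, which cannot be told apart from obesity here, since 0 groups separate food from obesity. Obesity itself as the cause stays a hypothesis. The list and the comparisons were chosen beforehand, but the tests of causes were chosen on these same data.

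Lymphocyte genes were high in 11 libraries and near 0 in 12. A lymph node in part of the samples may account for this, since stroma genes that lymphocytes do not make (Glycam1, Madcam1, Ccl21a, Chst4) moved with the B cell list, with a gap of 6.66 log2 units between the lowest library with it and the highest without. Glycam1 reached at least 124 CPM in the former and at most 0.458 CPM in the latter, and Cd79a 137 to 887 CPM against at most 1.79 CPM. Each of the 4 groups held libraries on both sides of this gap (high in 4 of 5 lean IgG2a, 3 of 5 lean anti-PD-1, 2 of 5 obese IgG2a and 2 of 8 obese anti-PD-1). This argues against diet or treatment alone as the source of the gap. Either could still shift how often these genes are high, which cannot be told apart from uneven dissection with so few libraries (Fisher's exact test over the 4 groups, two-sided p = 0.317; lean 7 of 10 against obese 4 of 13, exact p = 0.0995). No biological explanation was tested beyond the groups.

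The genes lower with anti-PD-1 in obese mice may come from the make-up of obese IgG2a libraries 2 and 5. The 22 liver genes were listed after the data were seen, and 13 of them are among the genes called lower. Their high values in library 5 are thus no independent support. Liver RNA in library 5 is a candidate source, since 22 of 22 liver genes were highest there (median 329 CPM, and 0.197 CPM over the other libraries; Alb 6363 CPM), of which 6 averaged at least 1 CPM in lean fat pad. Dividing tumor cells are another, since these libraries ranked 1 and 2 of 23 for the proliferation score, and Hmga2 (94.2 and 170 CPM), Fosl1 (103 and 121 CPM) and Mmp13 (26.7 and 30.4 CPM) were high in both; no tumor marker list was tested, and lymph node libraries came next in proliferation. A response shared by the treated mice cannot be told apart from these. Without libraries 2 and 5, 25.1% of the median was left (-4.16 before, -1.04 after, member SD 3.19 and 1.14), but 98 of the 106 genes had their highest value in those libraries, so leaving them out had to shrink it. Without them 103 of the 106 genes were still lower, 41 at an unadjusted p under 0.05. These genes were chosen as lower in a comparison that shares the treated and the remaining IgG2a libraries. Their selection thus favors a lower value here, and this count cannot speak for a shared response either.

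Chance was set against each count by 100 splits of the same libraries, the real one included. As many genes as in the real split came from 1 split for obesity with IgG2a (1152, highest other 673) and from 2 for obesity with anti-PD-1 (1999, highest other 5348). Counts this high were thus rare among the splits. With 100 splits and 5 comparisons these shares are coarse and unadjusted, and they do not separate obesity from uneven tissue make-up. For anti-PD-1 in obese mice 6 splits reached the real count (107, highest other 5437), so chance stays open there. In lean mice (highest other 2) and for the interaction (highest other 1730) the real count was 0, which all 100 splits reach by definition, so the splits decide nothing there. Splits with several times the real count point to a structure of the samples. For anti-PD-1 in obese mice, 5 other splits called at least 107 genes. In 4 of these (503, 2653, 3311 and 5437 genes) every library with a high B cell score fell on the same side, as in 12 of the 99 other splits, of which 8 called 0 genes, while the split with 2521 genes divided them. In the split with 5348 genes they also fell on the same side, as they did in 3 that called 0 genes. Lymph node tissue may thus be a part of that structure.

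The lists whose response differed between obese and lean mice are those with camera adjusted p values in the results. Their median differences were -2.12 for proliferation, -1.08 for type I interferon, -0.80 for macrophages, -0.58 for neutrophils, -0.30 for hypoxia, 0.86 for adipocyte markers, 1.74 for adipose expansion and 1.76 for epidermis (0.36 without lean IgG2a 5). None passed with an estimated correlation.

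The remaining values are given without explanation. Lean IgG2a 5 was lowest of its group for the B cell list (-1.39), the lymph node stroma list (-1.42), Cd79a (1.79 CPM), Glycam1 (0 CPM), Ccl21a (0.133 CPM) and Pdcd1 (0.0445 CPM). Obese IgG2a 3 was highest for the skeletal muscle list (4.84), Ckm (78.2 CPM) and Myh4 (53.9 CPM), and lowest for Fdft1 (34.8 CPM). Obese IgG2a 5 was highest for the complement list (6.69), the Schwann cell list (3.89), Alb (6363 CPM) and Apoh (221 CPM), and lowest for Adrb3 (41.6 CPM). Obese anti-PD-1 3 was lowest for Adipoq (306 CPM), Retn (126 CPM), Sfrp5 (63.1 CPM) and Fdft1 (20.9 CPM). Lean anti-PD-1 1 was highest for MHC class I (8.45), and lean anti-PD-1 4 lowest for neutrophil genes (-1.77).

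Liver genes under 4 CPM stood highest of their group in lean anti-PD-1 3, with CPM of 2.91 (Gc), 1.99 (Ahsg), 1.10 (Kng1), 0.874 (Ambp), 0.783 (Pzp), 0.693 (Fga), 0.497 (Cps1), 0.482 (Slco1b2), 0.422 (Mug1) and 0.301 (Bhmt). In obese anti-PD-1 4 these were 1.37 (Gc), 0.641 (Kng1), 0.427 (Fga), 0.387 (Apoh), 0.307 (Cps1), 0.214 (Bhmt) and 0.147 (Mug1). Ambp was highest in lean IgG2a 2 (0.0882 CPM), Slco1b2 in lean IgG2a 4 (0.0894 CPM), and Mat1a lowest in lean IgG2a 3 (0 CPM). Among the other genes, Acacb (447 CPM) and Insig1 (439 CPM) were lowest in lean IgG2a 4 and Prss57 highest in lean IgG2a 2 (0.0147 CPM). Lep (319 CPM) and Ptchd4 (0.534 CPM) were highest in lean anti-PD-1 2, and Cdkl4 in lean anti-PD-1 3 (0.211 CPM). In obese IgG2a 4, Serping1 (424 CPM) and B3gnt4 (0.430 CPM) were highest and Mvd (4.87 CPM) lowest. In obese anti-PD-1 mice, Fkbp5 was highest in library 2 (152 CPM), where Lgals2 was lowest (0 CPM), and Ifit1 was lowest in library 1 (5.91 CPM).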

How the results depend on the processing

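Fits with only the libraries above or below a B cell score of 4, and without obese IgG2a 2 and 5 together, were chosen only after the data were seen. The cause was not tested for any change below, apart from the smaller number of libraries in fits that left some out. Obesity with IgG2a gave 1152 genes, and 2075 with DESeq2, 4883 with voom quality weights, 3020, 310 and 564 with lymph node, epithelium and muscle covariates, 255 below and 1896 above that score, 293 without libraries 2 and 5 and 583 with only the groups compared. Obesity with anti-PD-1 gave 1999, and 3117 with DESeq2, 6392 with quality weights, 3607 with limma-trend on TPM, 59 and 1244 with epithelium and muscle covariates and 574 above. Anti-PD-1 in obese mice gave 107, and 70 without a filter, 49 with the stricter one, 400 with DESeq2, 0 with voom, 2704 with quality weights, 39 with length offsets, 0 with limma-trend, 619 and 40 with lymph node and muscle covariates, 767 below, 0 above, 0 without libraries 2 and 5 and 0 with only the groups compared. In lean mice 0 became 22 with DESeq2, 1 with quality weights, 2 below and 1 with only the groups compared. The interaction's 0 became 50, 1 with voom, 623 with quality weights and 2 below, and the fit with only the groups compared was not run, as it needs all 4. The other alternatives named in the methods stayed within 1.5 times.

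With 1 library left out the counts ranged from 495 to 1662 and 1108 to 2432 for obesity, from 0 to 643 for anti-PD-1 in obese mice, from 0 to 0 in lean mice and from 0 to 1 for the interaction. Lists called ranged over 16 to 19, 9 to 19, 11 to 23, 1 to 8 and 6 to 14, and the correlation of -0.36 over -0.498 to -0.250. It was -0.0132 with split controls, -0.656 over genes called for obesity with the shared libraries (simulated mean -0.520, two-sided permutation p = 0.777) and -0.363 with RLE. The list counts of 16, 12, 16, 2 and 8 became 2, 0, 0, 0 and 0 with an estimated correlation and 9, 7, 3, 0 and 0 with fry. They were 25, 26 and 7 above (obesity with IgG2a, obesity with anti-PD-1 and anti-PD-1 in lean mice), 8 in lean mice and 17 for the interaction below, 8 and 13 with the lymph node covariate, and 25 (anti-PD-1 in obese mice) and 15 (interaction) without libraries 2 and 5.

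Directions turned above the B cell score of 4. For obesity with anti-PD-1, matrix genes turned to -0.61, type I interferon to 0.51, MHC class I to 0.25, T cells to 0.78 and Rtp4 to 0.15. For anti-PD-1 in obese mice, adipocyte markers turned to -0.32, fatty acid synthesis to -0.16, M1-like to 0.19, interferon gamma to 0.25, endothelium to -0.054 and Slc2a1 to 0.15. The T cell list turned to 0.16 with the lymph node covariate. Mammary epithelium in lean mice turned to -0.076, and in the interaction adipocyte markers turned to -0.056, hypoxia to 0.28 and type I interferon to 0.14. Below the score, lean IgG2a has 1 library, assumed to vary like the other groups. Limma-trend shifted the median of all genes by 0.22, 0.36, 0.16 and 0.15 (both obesity comparisons, anti-PD-1 in obese mice, interaction), and the fit above by -0.13 for obesity with IgG2a, 0.17 and 0.16 for the latter, and the one below by -0.12 for anti-PD-1 in obese mice. Of the genes called for obesity, limma-trend put 536 up and 305 down with IgG2a and 3179 up and 428 down with anti-PD-1, against 532 and 620, and 1034 and 965; voom put 219 up and 645 down with IgG2a. No paired analysis was possible because each mouse has its own title number and the replicate numbers follow the deposited order. Depth limits genes with few counts, and simulated 2-fold changes were recovered in 4% to 23% of genes.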

Other observations

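In this part the fit without obese IgG2a 2 and 5 and the rank of the proliferation score were chosen as tests only after the results were seen, as were the tumor genes. Lists of T cell function and of several cell types passed in none of the comparisons. In obese against lean IgG2a mice, their medians were 0.30 for M2-like macrophages, 0.42 for MHC class II (camera downward), 0.07 for cytotoxic effectors (mean -0.05), 0.50 for checkpoint genes, 0.14 for immediate early genes and -0.01 for regulatory T cells. They were 0.06 for B cells, 0.61 for plasma cells, 0.07 for dendritic cells and 0.91 for lymph node stroma, in each of which camera pointed downward. They were 0.01 for adipose progenitors and fibroblasts (mean -0.09), -0.39 for Schwann cells and -0.95 for red blood cells (camera upward). With anti-PD-1 in obese mice the first 6 stood at -0.32, -0.63, -0.50, -0.37, -0.21 and 0.29 (camera downward for the last), and the next 4 at -0.36, -1.44, -0.32 and -1.35.

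Of genes picked for their values, Hmga2, an embryonic chromatin gene, was at 94.2, 19.0 and 170 CPM in obese IgG2a 2, 4 and 5 and at most 5.84 CPM elsewhere. Fosl1 was at 103, 17.2 and 121 CPM and Mmp13 at 26.7, 6.68 and 30.4 CPM in the same libraries. Mki67, which marks dividing cells, was at 44.7, 12.6 and 89.4 CPM there, and at 125 CPM in obese IgG2a 3, a library with a high B cell score. No list of tumor genes was tested.

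A hypothesis about treatment is that PD-1 blockade in obese mice lowered macrophage and cell cycle genes beyond those libraries. Without obese IgG2a 2 and 5 together the medians were -0.90 for macrophages (camera adjusted p = 1.3e-04) and -1.47 for proliferation (5.6e-08). Of the 3 obese IgG2a libraries then left, 2 have a high B cell score, against 2 of 8 treated ones, and the former have proliferation scores of 4.48 and 5.21 (ranks 5 and 3 of 23), so lymph node tissue could also give the difference in proliferation, whose median was -0.45 in the libraries with a high B cell score. The macrophage list stayed called in those libraries (-0.70), which hold neither library 2 nor 5, in the others (-0.76) and with the lymph node covariate (-0.77), which argues against lymph node tissue as its whole cause. The high B cell set holds only 2 obese libraries per treatment. In the other set the obese IgG2a side is libraries 2, 4 and 5, so that fit does not speak to a change beyond libraries 2 and 5. Library 4, also with raised Hmga2 (19.0 CPM), stayed in the fit without 2 and 5. Over all libraries both lists passed with fry (adjusted p = 0.0124 and 0.0376) but not with camera at an estimated correlation (0.173 and 0.307), so the hypothesis stays open.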
